A study of Mus musculus with 10 samples.

How the data were processed

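RNA was measured in mouse embryonic stem cells of the E14 line, grown per the labels in medium with LIF and a pair of kinase inhibitors (2i), in wild-type cells and in cells lacking Mettl3, Mettl14, Wtap or Zc3h13. Each of the 5 groups had 2 libraries, 10 in all, made from polyadenylated RNA with a stranded kit and sequenced from both ends. The deposited values are raw counts of reads per gene and per repeat family, in 1 list per library, with no normalization by the authors. The submitters' processing notes name STAR 2.7.0a, featureCounts 1.5.1, edgeR, limma and the mm10 build. They do not state which step made which values, how reads with several genomic positions were assigned, the strand setting, or which gene and repeat annotations were used. Counts of multi-copy gene families (Khdc1, Xlr, Zscan4, Tdpoz, Usp17l, Rhox and histone genes) and of repeat families are therefore uncertain in their assignment, and so are antisense or overlapping genes.

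The lists held 54087 genes and 1205 repeat families. Gene symbols were joined to the GENCODE M21 annotation of GRCm38 (mm10) for positions and gene types, and between 6.05% and 6.53% of the counts of a library came from names without a match. Total counts per library ran from 80514543 to 125051654, so that counting error was small for all but the weakest genes. Scaling factors lay between 0.976 and 1.02. Values are given as counts-per-million (CPM), relative to the gene counts of a library, after scaling, as mean ± SD over the 2 libraries of a group.

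Genes and families were tested together with edgeR 4.0.16 in R 4.3.3. The model had 1 coefficient per group, trimmed-mean (TMM) factors and library sizes from the genes, the filter filterByExpr at its defaults, and edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment and a threshold of 0.05. All 10 libraries entered each fit, which left 5 residual degrees of freedom. After the filter 19870 genes and 990 families were tested. Fold changes are log2 values with the standard error derived from the quasi-likelihood F statistic. Each knockout was compared with wild type and with each other knockout, and the mean of the 4 knockouts was compared with wild type. The p-values measure only the spread between the 2 libraries of a group, which may be technical replicates of the same cells, since the labels do not say whether they are separate cultures. The biological coefficient of variation was 4.52%.

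Gene lists were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2, a preset correlation between genes of 0.01, and adjustment over all lists and the 4 comparisons with wild type, or the 6 comparisons among knockouts. The test was repeated with an estimated correlation. The splits of changed genes into higher and lower depend on the scaling, and which direction holds more genes is not read as a result. Counts of changed members are given over all genes and families tested, and as adjusted over the list alone. Lists needed at least 5 tested members. The 24 lists were the m6A writer complex, m6A readers and erasers, naive pluripotency, formative and primed epiblast, two-cell-like, retroelement silencing factors, germline genes silenced by DNA methylation, primitive endoderm, trophoblast, mesoderm and primitive streak, neuroectoderm, fibroblast and feeder, interferon-stimulated genes, p53 targets, imprinted genes, retrovirus- and retrotransposon-derived genes, FGF-ERK response, WNT targets, unfolded protein and integrated stress response, glycolysis and hypoxia, cholesterol synthesis, cytoplasmic ribosomal proteins, replication-dependent histones, and mitochondrially encoded mRNAs.

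The groups, the tests, the lists, the alternatives and the rule for named genes were fixed before the data were examined. Named are the 4 targeted genes. In each comparison with wild type the rule takes the 8 genes with the largest rise and the 8 with the largest fall among those past the threshold with a mean of at least 1 CPM and no overlap between the groups' libraries. It also takes 10 genes in each direction among those changed alike in all 4 knockouts, ranked by their smallest fold change, 3 in each direction per pair of knockouts, and up to 4 members per list with the smallest adjusted p. Predicted genes, clone names and pseudogenes were skipped. Fewer genes are named in the text, from the top of each ranking. Nanog, Pou5f1, Sox2 and Klf2 and the families MMERVK10D3_I-int, ETnERV3-int and IAPLTR2_Mm were chosen for mention after their values were seen. So were the genes named only under other observations.

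The other settings tried were scaling by the relative log expression or upper-quartile methods, library size without scaling, DESeq2 1.42.0, limma-voom, no filter, a filter of at least 1 CPM in 2 libraries, an adjusted p under 0.01, an added absolute log2 fold change of at least 1, only the groups compared, the replicate number as a block, each library left out in turn, library sizes from all counts for the families, and camera on voom-weighted values. Counts and list tests without the genes of chromosomes 6 and 8 were added after the data had been seen.

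Where a group had 0 reads of a gene, the fold change is given as a lower bound against a floor of 3 counts over the group. Where it had 1 to 3 reads, the ratio of counts is given with its exact 95% interval. Such intervals and floors cover counting error only. As the comparisons share the wild-type libraries, 20 sets of 5 groups without any change were simulated for comparison, with all 10 libraries, the wild-type ones included, drawn around 1 mean per gene.

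The pipeline was tested on counts simulated for all libraries from their joint means and spread, with 50 genes changed in Mettl3 knockout at each of 4 sizes. It recovered 21 of 50 genes changed by 1.25-fold, 25 by 1.5-fold, 36 by 2-fold and 46 by 4-fold. There were 10 false calls among 20640 unchanged entries, and camera called 0 of 100 unchanged lists. Genes were drawn independently and few were changed, unlike in the data, so that these rates need not hold there. Tables were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures with matplotlib 3.10.9. Sequence reads were not used here, so that deletions, karyotypes and the positions of retroviral copies were not examined. Virma and Resf1 were not in the lists of counts under those names and were not analysed here.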

Results

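Polyadenylated RNA of mouse embryonic stem cells was counted per gene and per repeat family in wild-type cells and in 4 knockouts of the m6A writer complex, with 2 libraries per group. Mettl3 is the catalytic subunit that methylates adenosine in mRNA, Mettl14 its partner in RNA binding, and Wtap and Zc3h13 are regulatory subunits. Total counts of replicates 1 and 2 were 92899127 and 81150870 in wild type, 88726119 and 111372043 in Mettl3 knockout, 114761585 and 81043565 in Mettl14 knockout, 101463252 and 80514543 in Wtap knockout, and 102852351 and 125051654 in Zc3h13 knockout. Between 24792 and 26942 genes had reads in a library, and repeat families took 2.15% to 2.99% of the counts. Log2 CPM of the replicates of a group correlated at 0.999 to 1.00 across genes. Their spread relative to counting error was unequal among groups. The chi-square per degree of freedom over genes with at least 20 reads was 8.81 in wild type. It was 4.21, 25.1, 10.3 and 2.82 in Mettl3, Mettl14, Wtap and Zc3h13 knockouts. The groups share 1 estimate of spread per gene, which may be too small for Mettl14 knockout. The first principal component held 61.3% of the variance and separated wild type, at −126 in both libraries, from Mettl3 knockout at 54.0 and 55.4, Mettl14 knockout at 67.7 and 66.5 and Zc3h13 knockout at 41.6 and 40.9, with Wtap knockout at −36.5 and −37.4.

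Zc3h13 (chromosome 14, 75284373 to 75344426) was the targeted gene whose mRNA was reduced strongly in its own knockout, from 97.0 and 98.3 CPM in the wild-type libraries to 22.6 and 22.9 CPM (log2 fold change −2.10, SE 0.044, n = 2, adjusted p = 2.8e-13). Its level in the other libraries was 106 and 109 CPM in Mettl3 knockout, 120 and 126 CPM in Mettl14 knockout and 108 and 109 CPM in Wtap knockout. Mettl3 (chromosome 14, 52294841 to 52305128) had 42.0 and 40.1 CPM in wild type, 30.8 and 30.9 in its own knockout, 29.7 and 29.6 in Mettl14 knockout, 37.1 and 35.4 in Wtap knockout and 24.8 and 24.5 in Zc3h13 knockout, so that its fall was larger in Zc3h13 knockout (−0.74) than in its own (−0.41). Mettl14 (chromosome 3, 123368297 to 123386108) rose in its own knockout, from 42.3 and 43.9 CPM to 60.3 and 59.5 CPM (0.47). It had 38.3 and 39.7 CPM in Mettl3 knockout, 41.9 and 39.9 in Wtap knockout and 34.1 and 34 in Zc3h13 knockout. Wtap (chromosome 17, 12966796 to 12994169) rose in all 4 knockouts, from 143 and 131 CPM to 232 and 254 CPM in its own (0.83), 309 and 329 in Mettl3 knockout (1.22), 358 and 397 in Mettl14 knockout (1.46) and 368 and 364 in Zc3h13 knockout (1.42). The labels give no deletion sites, and a deletion need not lower the mRNA, so that mRNA levels checked the label of the Zc3h13 knockout alone.

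**Figure D1:**
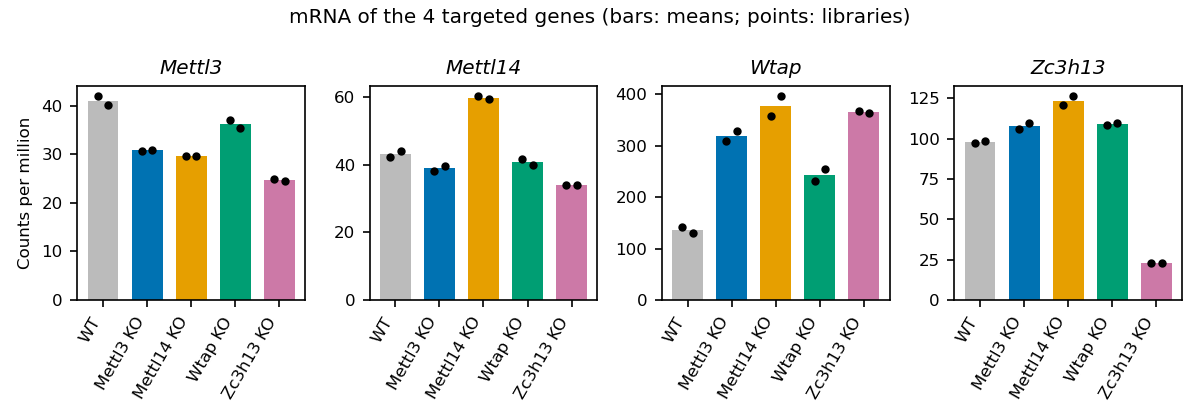
Counts-per-million (CPM) of the mRNAs of the 4 targeted genes in wild type and each knockout. Bars are group means and points are the 2 libraries. Zc3h13 fell to 22.6 and 22.9 CPM in its own knockout, while Mettl14 and Wtap were higher in their own knockouts than in wild type.

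Rbm15, which recruits the writer complex to RNA, rose from 36.9 ± 0.77 CPM to 121 ± 1.2, 136 ± 7.0, 74.0 ± 2.6 and 118 ± 1.4 CPM in Mettl3, Mettl14, Wtap and Zc3h13 knockouts (SD, n = 2). Values of the 4 knockouts follow this order throughout, and values in brackets after a gene are log2 fold changes against wild type. The writer subunits Cbll1 (0.72, 0.81, 0.59 and 0.47) and Rbm15b (0.64, 0.62, 0.47 and 0.19) rose as well. The 7 measured members of the m6A writer complex include the 4 targeted genes, whose own deletion can move the list. Of these 7 members, 5, 6, 5 and 4 rose and 2, 1, 1 and 3 fell, in the same order of knockouts (7, 7, 6 and 7 adjusted over the list alone). The list passed in Mettl14 knockout (camera adjusted p = 0.0434, and adjusted p = 0.515 with an estimated correlation), but not after leaving out wild-type replicate 1 (0.0562), wild-type replicate 2 (0.0515), Zc3h13 knockout replicate 1 (0.0508) or Zc3h13 knockout replicate 2 (0.0506), with upper-quartile scaling (0.0548) or under the filter of at least 1 CPM in 2 libraries (0.0912). Its adjusted p was 0.243, 0.171 and 0.9 in the Mettl3, Wtap and Zc3h13 knockouts. Among m6A readers and erasers, Ythdf2, a reader that promotes decay of methylated mRNA, rose from 100 ± 1.5 CPM to 279, 334, 180 and 307 CPM. Igf2bp2 (1.30, 1.31, 1.28 and 1.36) and the nuclear reader Ythdc1 (1.03, 1.36, 0.56 and 1.11) rose too, while Igf2bp3 on chromosome 6 fell in all 4 (−1.03, −1.21, −0.55 and −1.02). Of 13 readers and erasers 5, 7, 7 and 6 rose and 3, 3, 4 and 4 fell (7, 10, 11 and 10 changed adjusted over the list alone), and the list passed in none (adjusted p 0.407, 0.174, 0.359 and 0.454).

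Genes of chromosomes 6 and 8 were for the most part lower in every knockout than in wild type. In Mettl3, Mettl14, Wtap and Zc3h13 knockouts 947, 951, 1027 and 954 of them were called lower and 303, 331, 186 and 303 higher. The median log2 fold change of 721 tested genes of chromosome 6 was −0.68, −0.71, −0.73 and −0.70 in Mettl3, Mettl14, Wtap and Zc3h13 knockouts, and that of 779 genes of chromosome 8 was −0.39, −0.44, −0.40 and −0.43. Medians of the other chromosomes lay between −0.07 and 0.17, but single 20 Mb windows went further. On chromosome 10, the 156 genes at 60 to 80 Mb had a median of −0.712 in Wtap knockout against wild type. Among genes named below with their positions, Col13a1 and Aire lie there, Aire being named for its fall in Mettl3 knockout. Other named genes and list members may lie there too, and the genes of this window were not taken out of any list test. At 40 to 60 Mb the median was 0.745 and 0.683 in Mettl14 and Mettl3 knockouts against Wtap knockout. Windows of other chromosomes reached 0.848 against wild type. In comparisons between knockouts, the chromosome 6 median was at most 0.04 from 0 and the chromosome 8 median at most 0.03. That of chromosome X was 0.165 in Mettl3 against Zc3h13 knockout, with 30.0% of its 583 genes lower. The 1500 genes of chromosomes 6 and 8 were 7.55% of the genes tested and 13.8%, 13.0%, 17.2% and 13.6% of those called lower. Whether a named gene lies on either chromosome is given beside its value.

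**Figure D2:**
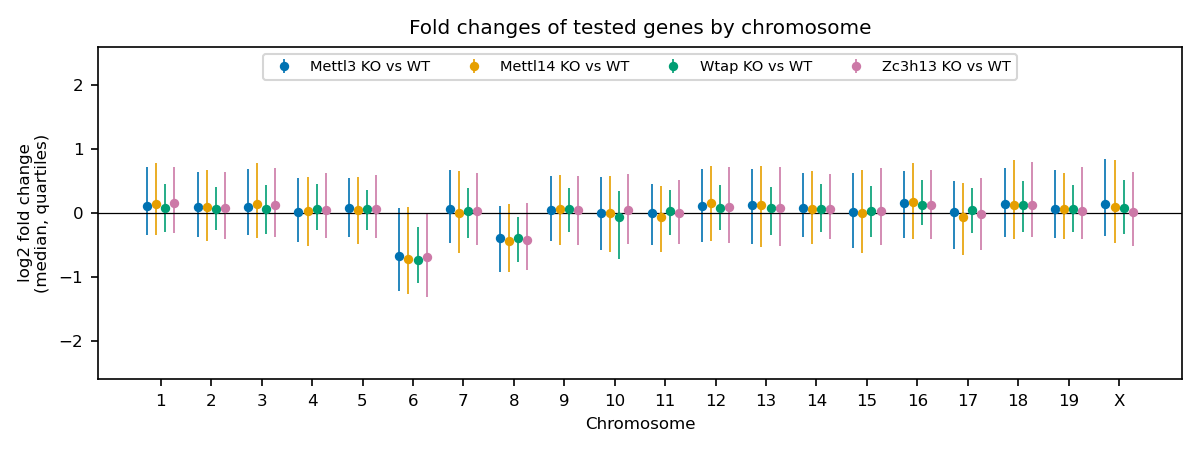
Log2 fold changes of tested genes by chromosome, knockout against wild type. Points are medians and bars span the quartiles. Chromosome 6, with medians of −0.68 to −0.73, and chromosome 8, with −0.39 to −0.44, lay below the others in all 4 comparisons.

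The comparison of the 4 knockouts with wild type asked which transcripts change when the writer complex is lost. Khdc1a (chromosome 1, 21349641 to 21352200), of a family of KH-domain proteins of the oocyte and early embryo, had 0.039 ± 0.038 CPM in wild type and 29.2 ± 1.2, 11.2 ± 0.71, 12.1 ± 0.96 and 22.8 ± 0.69 CPM in Mettl3, Mettl14, Wtap and Zc3h13 knockouts (SD, n = 2). Isx (chromosome 8, 74873173 to 74893506), a homeobox gene of the intestine, had 0 reads in wild type and was at least 160-, 98.9-, 9.21- and 46.7-fold higher. Lmo3 (chromosome 6, 138362918 to 138581968), a LIM-domain cofactor, also had 0 reads in wild type and was at least 114-, 248-, 6.25- and 10.5-fold higher. Pde4b (chromosome 4, 102087543 to 102607259), a cAMP phosphodiesterase, had count ratios to wild type of 379 (95% interval 105 to 3130), 473 (131 to 3910), 91.3 (24.9 to 759) and 188 (51.9 to 1560). In the other direction, Cbln1 (chromosome 8, 87468405 to 87472609), a secreted protein of the synapse, fell (log2 fold changes −7.66, −6.55, −4.19 and −6.59). Padi2 (chromosome 4, 140906344 to 140952586), which converts arginine to citrulline, fell from 62.2 ± 1.5 CPM to 0.81 ± 0.073, 1.37 ± 0.26, 3.67 ± 0.067 and 2.00 ± 0.24 CPM. Col13a1 (chromosome 10, 61838236 to 61979108), a transmembrane collagen, and Coro6 (chromosome 11, 77462411 to 77470484), an actin-binding coronin, fell in all 4, with smallest changes of −4.81 and −4.52.

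In total 7938 genes changed in the same direction in all 4 knockouts, 3927 higher and 4011 lower, where lists of the same sizes drawn independently would share 295 and 268. A further 1992 genes were called in opposite directions in different knockouts, and 2080 were called in none. For the mean of the 4 knockouts, 14498 genes changed (7209 higher, 7289 lower), 5505 of them at least 2-fold. All comparisons share the wild-type libraries. In simulated groups without any change that shared a simulated control, 0.05 genes were called alike in all 4 on average. A simulated comparison called only 1.1 genes on average, so that this overlap was bound to be small. It does not show how far shared controls raise the observed overlap. The 4 fold changes of a gene had the same sign in 40.8% of simulated genes against 65.7% observed. Fold changes correlated across genes, which are not independent replicates, at 0.93 between Mettl3 and Mettl14 knockouts, 0.78 between Mettl3 and Wtap, 0.90 between Mettl3 and Zc3h13, 0.70 between Mettl14 and Wtap, 0.87 between Mettl14 and Zc3h13 and 0.76 between Wtap and Zc3h13. The simulated correlations were 0.526, 0.515, 0.539, 0.515, 0.539 and 0.528 in the same order. The covariances were 2.34, 1.35, 2.08, 1.26, 2.11 and 1.27, against 0.036 simulated for each pair. The wild-type group is too small to be split into parts with replicates, and part of the excess over independent lists may come from the shared controls. The simulation covers only the spread between libraries. A lasting difference of the single wild-type line would enter all 4 comparisons. The design cannot tell it apart from a shared effect of the knockouts.

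Endogenous retroviruses of the IAP class are normally silenced in stem cells by the histone methyltransferase Setdb1 and DNA methylation. Their internal sequence IAPEz-int rose in all 4 knockouts, from 207 ± 5.4 CPM in wild type to 404 ± 0.0038 CPM in Mettl3 knockout (log2 fold change 0.96, SE 0.056, n = 2, edgeR adjusted p = 3.68e-09), 303 ± 19 CPM in Mettl14 knockout (0.55), 319 ± 23 CPM in Wtap knockout (0.62) and 459 ± 13 CPM in Zc3h13 knockout (1.15). The long terminal repeat IAPLTR1_Mm, a promoter of IAP elements, rose by 0.87, 0.51, 0.49 and 1.03. Another IAP long terminal repeat, IAPLTR2_Mm, had 2.79 ± 0.45 CPM in wild type and 2.83, 1.93, 2.38 and 2.66 CPM in the knockouts. Of 25 IAP families 16, 9, 15 and 14 rose, 3, 4, 0 and 2 fell and 6, 12, 10 and 9 did not pass, and their summed level went from 286 CPM to 570, 426, 489 and 640 CPM. Between knockouts, IAPEz-int was lower in Mettl14 than in Zc3h13 knockout (−0.60, adjusted p = 1.4e-06), and lower in Wtap than in Zc3h13 knockout (−0.53, 3.06e-06). In the first of these pairs all 990 families had a median of −0.32 and 17 SINE families −0.24, so that part of the difference was common to repeats. In the second the medians were −0.05 and −0.04. MMERVK10D3_I-int, an internal retroviral sequence, rose from 20.1 ± 0.43 CPM to 61.8, 46.3, 91.0 and 85.2 CPM.

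Other retrotransposons went in several directions. MMETn-int, the internal sequence of the MusD and ETn elements, rose in Mettl3 (0.53, SE 0.10), Wtap (0.52) and Zc3h13 (0.96) knockouts and was 0.13 in Mettl14 knockout (adjusted p = 0.267), from 3240 ± 190 CPM in wild type. The related ETnERV3-int fell from 555 ± 39 CPM to 9.60, 8.61, 11.3 and 14.6 CPM. Of the 4 MMETn and ETn families 3, 1, 3 and 3 rose and 1 fell in each knockout. MERVL-int, a retrovirus expressed in the embryo at the stage of zygotic genome activation, fell (−0.77, −0.55, −0.58 and −1.19). Of 8 MERVL and MT2 families 2, 0, 3 and 2 rose and 3, 4, 2 and 3 fell. The young LINE family L1MdA_I fell from 401 ± 26 CPM to 62.1, 68.1 and 82.5 CPM in Mettl3, Mettl14 and Zc3h13 knockouts and was 367 ± 32 CPM in Wtap knockout (−0.13, adjusted p = 0.202). The difference between Wtap and Zc3h13 knockouts was 2.16 (adjusted p = 2.94e-10). Of 25 L1Md families 8, 9, 13 and 6 rose and 10, 13, 1 and 8 fell. RLTR45-int rose in Wtap knockout from 27.3 ± 1.2 to 131 ± 24 CPM (2.26), fell in Mettl3 (−0.89) and Mettl14 (−0.80) knockouts, and was 0.06 in Zc3h13 knockout (adjusted p = 0.561). Of 10 RLTR10 families 7, 4, 6 and 6 rose and 2, 1, 1 and 1 fell, and of 5 MMVL30 and RLTR6 families 2, 1, 2 and 4 rose and 1, 2, 0 and 0 fell. Of 17 SINE families of the B1 to B4 classes 0, 0, 0 and 1 rose and 2, 10, 0 and 2 fell. Over all 990 families, 406, 500, 312 and 413 changed (222, 150, 232 and 276 higher), and 136 changed alike in all 4. The 184 lower families in Mettl3 knockout were 121 without wild-type replicate 2. The 80 lower ones in Wtap knockout were 53 without wild-type replicate 2, 121 without Wtap knockout replicate 1 and 53 without Wtap knockout replicate 2, and the 137 lower ones in Zc3h13 knockout were 91 without wild-type replicate 2. Reads of a family may come from copies inside or near genes, which the counts do not separate.

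**Figure D3:**
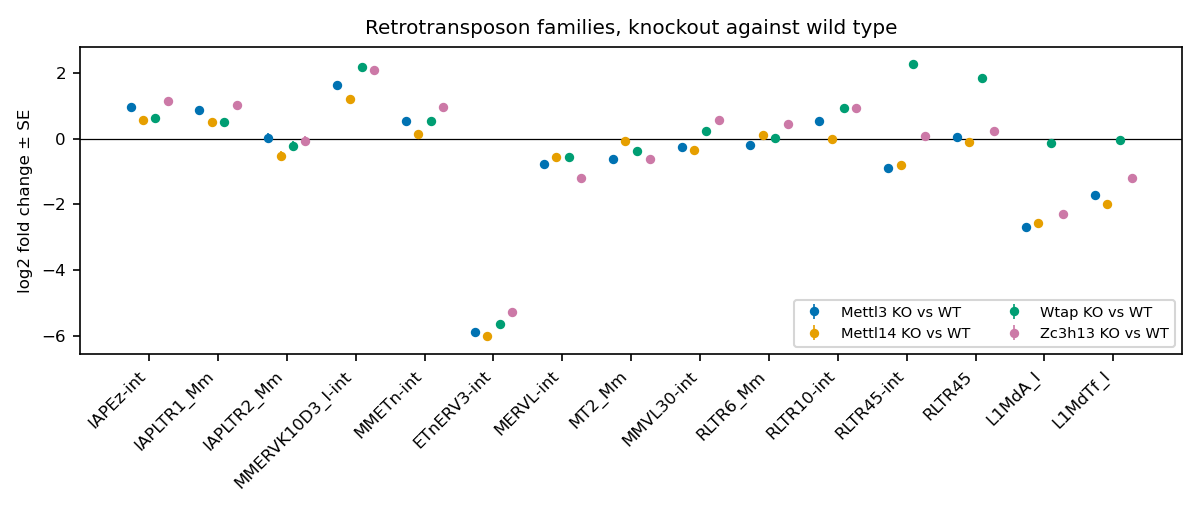
Log2 fold change of named retrotransposon families, knockout against wild type. Points are fitted values and bars are standard errors, from 2 libraries per group. IAPEz-int and MMERVK10D3_I-int lay above 0 and ETnERV3-int and MERVL-int below 0 in all 4 comparisons, while RLTR45-int rose in Wtap knockout alone among the 4 and L1MdA_I fell in the other knockouts.

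Factors that silence retroelements were changed in part. Setdb1 rose from 198.4 ± 2.3 CPM by 1.33, 1.34, 0.54 and 1.38 (SE 0.041), and Zfp809, a zinc-finger protein that binds retroviral primer sites, rose by 1.36, 1.12, 1.41 and 1.66. Cbx3 (−0.91, −0.74, −0.73 and −0.94) and Smarcad1 (−0.69, −0.81, −0.57 and −0.53), both on chromosome 6, fell. Of 25 such factors 13, 12, 15 and 12 rose and 8, 7, 5 and 7 fell (22, 19, 20 and 19 changed adjusted over the list alone), and the list did not pass (adjusted p 0.423, 0.423, 0.174 and 0.575). Of 15 retrovirus- and retrotransposon-derived genes 7, 8, 6 and 5 rose and 5, 5, 3 and 4 fell (12, 13, 9 and 9 adjusted over the list alone; adjusted p 0.632, 0.575, 0.423 and 0.949). Peg10, on chromosome 6, rose in Mettl3 (1.60) and Mettl14 (2.55) knockouts, and Arc fell in all 4 (−1.78, −1.59, −0.91 and −1.06).

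Several metabolic groups fell together in all 4 knockouts. Slc2a3, a glucose transporter on chromosome 6, fell from 2890 ± 26 CPM to 650, 623, 988 and 323 CPM, and the phosphofructokinase Pfkp fell from 420 ± 3.1 CPM to 40.6, 49.9, 196 and 80.7 CPM. Pfkm, the muscle isoform of the same enzyme, rose from 17.2 ± 0.64 CPM to 90.5, 80.2, 64.4 and 124 CPM. Of 25 glycolysis and hypoxia genes 22, 22, 21 and 22 fell and 3, 3, 1 and 3 rose (25, 25, 22 and 25 changed adjusted over the list alone), with medians of −0.86, −0.75, −0.74 and −0.96. The camera adjusted p was 1.64e-05, 0.000112, 1.25e-05 and 1.64e-05, and adjusted p = 0.515, 0.535, 0.515 and 0.515 with an estimated correlation. Without the 5 members on chromosomes 6 and 8 the medians were −0.73, −0.67, −0.55 and −0.81. In the unfolded protein and integrated stress response, Trib3, a pseudokinase induced by ATF4, fell from 46.7 ± 1.4 CPM to 12.5, 6.48, 20.3 and 10.4 CPM. Asns, the asparagine synthetase on chromosome 6, fell (−1.18, −1.21, −0.73 and −1.59). Of this list's 20 genes 18, 16, 15 and 16 fell and 1, 2, 0 and 1 rose (19, 18, 15 and 17 adjusted over the list alone; medians −0.91, −0.71, −0.58 and −0.99). Its adjusted p was 3.28e-05, 0.000609, 5.22e-05 and 8.99e-05, and adjusted p = 0.515, 0.536, 0.515 and 0.515 with an estimated correlation. In cholesterol synthesis, Lss, the lanosterol synthase, fell (−1.15, −1.03, −1.11 and −1.13), and Msmo1 on chromosome 8 (−1.39, −1.17, −1.30 and −1.22). Of 22 such genes 18, 17, 18 and 19 fell and 2, 3, 1 and 1 rose (20, 20, 19 and 20 adjusted over the list alone; medians −0.62, −0.53, −0.51 and −0.61). The adjusted p was 0.000216, 0.00248, 1.64e-05 and 0.000112, and adjusted p = 0.515 with an estimated correlation in each.

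Among the histone genes, Hist1h2bj fell from 1.72 CPM in wild type to 0.23, 0.11, 0.27 and 0.18 CPM. H1f0, a replacement histone with a polyadenylated mRNA, rose in Mettl3 (1.23), Mettl14 (1.64) and Zc3h13 (1.10) knockouts. Of 58 members of the list of replication-dependent histones, which also took in H1f0, 36, 27, 38 and 36 fell and 6, 5, 0 and 6 rose (43, 29, 40 and 42 adjusted over the list alone, with medians of −1.16, −0.96, −1.23 and −1.34). The libraries were made from polyadenylated RNA, in which mRNAs without a poly(A) tail leave few reads. Only 7 members passed the filter of at least 1 CPM in 2 libraries. The list passed in Mettl3, Wtap and Zc3h13 knockouts (adjusted p = 0.0122, 6.03e-05 and 0.027; adjusted p = 0.515, 0.515 and 0.536 with an estimated correlation) and had 0.0846 in Mettl14 knockout, where it passed without wild-type replicate 2 (0.0222), Mettl3 knockout replicate 1 (0.0434) or replicate 2 (0.0393), Mettl14 knockout replicate 2 (0.033) or Wtap knockout replicate 1 (0.0425), with adjusted p = 0.64 from all libraries with an estimated correlation. Without the genes of chromosomes 6 and 8 it passed there too (adjusted p = 0.0434, and adjusted p = 0.485 with an estimated correlation). With a filter of at least 1 CPM in 2 libraries, 7 members remained in Mettl3 knockout, with a median of 0.38 (adjusted p = 0.946), and the list passed neither in Wtap (0.0686) nor in Zc3h13 knockout (median −0.29). Notum, a secreted inhibitor and target of WNT signalling, rose from 27.6 ± 1.7 CPM to 402, 368, 158 and 356 CPM, and Lef1, a transcription factor of the pathway, from 7.42 ± 0.49 CPM to 65.1, 50.5, 49.3 and 36.7 CPM. Of 17 WNT targets 12, 10, 13 and 11 rose and 4, 4, 3 and 5 fell (16, 14, 16 and 16 adjusted over the list alone; medians 0.92, 0.56, 0.81 and 0.68). The list passed in Mettl3 and Wtap knockouts (adjusted p = 0.0339 and 0.00598, and adjusted p = 0.515 in both with an estimated correlation), and had 0.159 and 0.28 in Mettl14 and Zc3h13 knockouts. Without the genes of chromosomes 6 and 8 it passed in Mettl14 knockout too (adjusted p = 0.0309, and adjusted p = 0.473 with an estimated correlation).

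**Figure D4:**
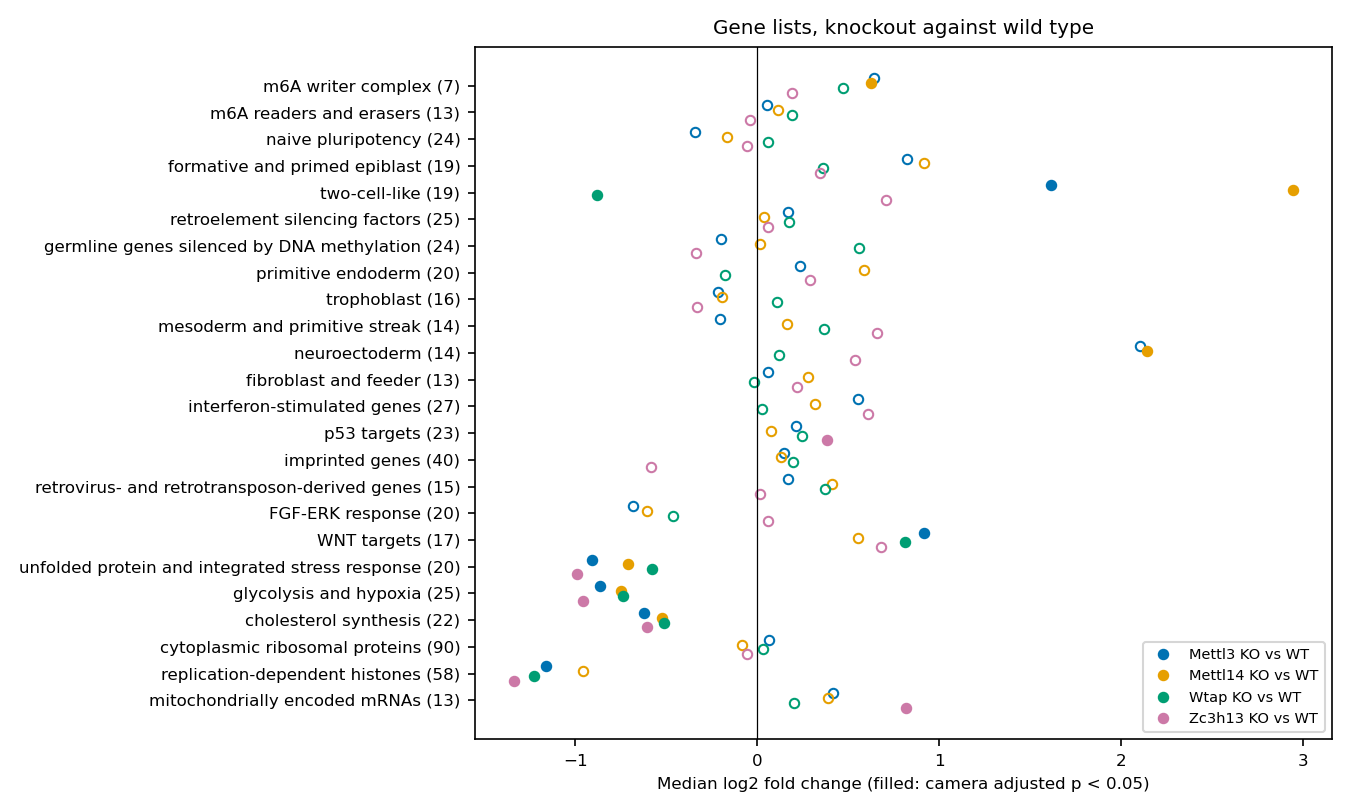
Median log2 fold change of the tested members of the 24 gene lists, with the number of members in brackets, knockout against wild type. Filled points passed the camera test with the preset correlation, and open points did not. The stress response, glycolysis and cholesterol lists lay below 0 and passed in all 4 comparisons, with adjusted p = 0.515 to 0.536 with an estimated correlation. The two-cell-like list lay at 1.61 and 2.94 in Mettl3 and Mettl14 knockouts and at −0.88 in Wtap knockout.

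The Mettl3 knockout against wild type asked what the loss of the catalytic subunit changes. Foxa2 (chromosome 2, 148042877 to 148046969), a pioneer transcription factor of the endoderm, had 1 read in both wild-type libraries together and 6.47 ± 0.78 CPM in the knockout (count ratio 1120, 95% interval 201 to 44200). Ptn (chromosome 6, 36714929 to 36810220), a heparin-binding growth factor, rose from 0.046 to 21.1 ± 0.28 CPM (log2 fold change 8.78, SE 0.20, n = 2). Kctd12b had a count ratio of 460 (127 to 3810). The peptide hormone gene Adm2 fell (−6.57), and so did Aire (chromosome 10, 78030022 to 78043610), the autoimmune regulator of the thymus (−6.53). Dppa3 on chromosome 6, a maternal factor that protects DNA methylation in the zygote, rose from 1.77 ± 0.044 to 158 ± 3.2 CPM, and Tdgf1, a co-receptor of Nodal, fell from 646 ± 5.6 to 32.8 ± 0.21 CPM. In total 14036 genes changed, 7190 higher and 6846 lower, or 70.6% of those tested, and 6072 changed at least 2-fold. Of 24 genes of naive pluripotency 8 rose and 14 fell (22 adjusted over the list alone; median −0.34, adjusted p 0.257). Pou5f1 was at 0.03 and did not pass in any knockout, Nanog on chromosome 6 fell by 0.45, and Sox2 (0.58) and Klf2 on chromosome 8 (1.40) rose. Of 20 FGF-ERK response genes 5 rose and 11 fell (17 adjusted over the list alone; median −0.69, adjusted p 0.0966), among them Etv4 from 136 ± 2.7 to 10.3 CPM and the feedback inhibitor Spry4 (−3.30). Of 19 two-cell-like genes, which mark cells resembling the embryo at zygotic genome activation, 13 rose and 0 fell (13 adjusted over the list alone; median 1.61), among them Zscan4b from 0.31 to 1.18 CPM. That list passed at an adjusted p of 0.0114, and adjusted p = 0.515 with an estimated correlation, but not under the filter of at least 1 CPM in 2 libraries (0.0513). MERVL-int, a retroviral marker of the same state, fell (−0.77), and of 8 MERVL and MT2 families 2 rose and 3 fell. Of 14 neuroectoderm genes 9 rose and 4 fell (13 adjusted over the list alone; median 2.10, adjusted p 0.202), among them Map2 (3.4), Sox11 (2.69) and Pax6 (4.93).

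The Mettl14 knockout against wild type asked the same of the RNA-binding partner. Cdh13 (chromosome 8, 118283733 to 119324921), a cadherin without a cytoplasmic domain, rose from 0.023 to 19.7 ± 1.8 CPM (log2 fold change 9.64, SE 0.18, n = 2). Ptn rose to 25.6 ± 0.75 CPM (9.06), Rassf9 (chromosome 10, 102512222 to 102549736) rose by 8.75, and Fam196b (chromosome 11, 34314822 to 34422640) had a count ratio of 1150 (206 to 45500). Xlr5a (chromosome X, 73107635 to 73292976), of a multi-copy X-linked family, fell from 8.86 ± 0.53 to 0.069 ± 0.0080 CPM. In total 14475 genes changed, 7129 higher and 7346 lower, or 72.9%, and 6576 changed at least 2-fold. All 19 two-cell-like genes rose (19 adjusted over the list alone; median 2.94, adjusted p = 3.47e-05, and adjusted p = 0.515 with an estimated correlation), among them Zscan4c from 0.53 to 5.86 ± 0.14 CPM and Zscan4b from 0.31 to 4.23 ± 0.058 CPM. MERVL-int, the retroviral marker of the same state, fell (−0.55), and of 8 MERVL and MT2 families 0 rose and 4 fell. All 990 families had a median of −0.22 in this knockout, so that part of the fall was common to repeats. Of 14 neuroectoderm genes 11 rose and 2 fell (13 adjusted over the list alone; median 2.14), among them the eye and forebrain regulator Pax6 from 0.31 to 15.6 ± 0.37 CPM, Sox11 (2.98) and Map2 (3.33). The list passed at an adjusted p of 0.015, and adjusted p = 0.515 with an estimated correlation, but not under the filter of at least 1 CPM in 2 libraries (0.177). Of 24 naive genes 8 rose and 13 fell (21 adjusted over the list alone; median −0.17, adjusted p 0.431). Of 20 FGF-ERK genes 7 rose and 11 fell (18 adjusted over the list alone; median −0.61, adjusted p 0.382). Among the imprinted genes, Slc38a4 (−3.37) and Plagl1 (−5.69) fell.

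The Wtap knockout against wild type asked what the loss of this regulatory subunit changes, and fewer genes changed at least 2-fold than in the other knockouts. Fgf10 (chromosome 13, 118669791 to 118792115), a growth factor of limb and lung buds, fell from 28.2 ± 0.94 to 1.51 ± 0.25 CPM (log2 fold change −4.21, SE 0.10, n = 2), and Kcnn1 (−4.16) and Crispld2 (−4.04), both on chromosome 8, fell as well. Dcdc2a (chromosome 13, 25056004 to 25210706), a microtubule-binding protein gene, rose from 0.040 to 2.85 ± 0.051 CPM (6.08), and Khdc1b had a count ratio of 180 (31.8 to 7130). In total 12200 genes changed, 6248 higher and 5952 lower, or 61.4%, and 3966 changed at least 2-fold. Dppa3 rose by 4.95 and Tdgf1 fell by 1.89, and of 24 naive genes 11 rose and 10 fell (22 adjusted over the list alone; median 0.06, adjusted p 0.715). Of 19 two-cell-like genes 0 rose and 7 fell (3 adjusted over the list alone; median −0.88), among them Zscan4a (−1.83) and Zscan4f (−1.25). Tcstv3 had 0 reads in this knockout and was at least 3.72-fold lower than in wild type. The list passed at an adjusted p of 0.017, and adjusted p = 0.515 with an estimated correlation, but not without Wtap knockout replicate 2 (0.0515), under the filter of at least 1 CPM in 2 libraries (0.0912) or with voom weights (0.165). Of 20 FGF-ERK genes 4 rose and 8 fell (12 adjusted over the list alone; median −0.46, adjusted p 0.174), with lower Spry4 (−2.72) and Etv4 (−1.65). Of 14 neuroectoderm genes 5 rose and 5 fell (10 adjusted over the list alone; median 0.12, adjusted p 0.936).

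The Zc3h13 knockout against wild type asked the same of the other regulatory subunit. Pla2g1b (chromosome 5, 115466262 to 115474722), a secreted phospholipase, fell from 27.8 ± 1.3 to 0.29 ± 0.13 CPM (log2 fold change −6.52, SE 0.15, n = 2). Xlr5b (−7.93), Xlr5a (−7.21) and Adm2 (−6.89) fell, and Cyp1b1 (chromosome 17, 79701537 to 79715061), a cytochrome of oestrogen metabolism, rose from 0.072 to 15.4 ± 0.24 CPM (7.75). Rassf9 rose by 8.44. In total 14255 genes changed, 7222 higher and 7033 lower, or 71.7%, and 6034 changed at least 2-fold. Of 23 p53 targets 14 rose and 2 fell (16 adjusted over the list alone; median 0.38), among them the apoptosis effector Perp from 3.17 ± 0.27 to 18.4 ± 1.0 CPM and the kinase Plk2 (1.86). That list passed at an adjusted p of 0.0142, and adjusted p = 0.535 with an estimated correlation. In Mettl3, Mettl14 and Wtap knockouts 14, 10 and 15 p53 targets rose and 7, 5 and 5 fell (21, 15 and 20 adjusted over the list alone; adjusted p 0.28, 0.373 and 0.124). Of 13 mitochondrially encoded mRNAs 9 rose and 0 fell (9 adjusted over the list alone; median 0.82), among them mt-Nd3 from 257 ± 16 to 579 ± 3.3 CPM, and the group took 2.96% and 3.0% of the counts against 1.96% and 2.11% in wild type. It passed at an adjusted p of 0.0339, and adjusted p = 0.75 with an estimated correlation, but not without wild-type replicate 1 (0.0706) or under the filter of at least 1 CPM in 2 libraries (0.0686). In the other knockouts 7, 6 and 6 of these mRNAs rose and 0, 1 and 0 fell (7, 7 and 6 adjusted over the list alone; adjusted p 0.174, 0.251 and 0.243), and the list passed in Wtap knockout without its replicate 2 (0.0352), with adjusted p = 0.75 from all libraries with an estimated correlation. Two-cell-like genes had 7 higher and 0 lower (7 adjusted over the list alone; median 0.71, adjusted p 0.208). Of 24 naive genes 11 rose and 11 fell (23 adjusted over the list alone; adjusted p 0.993), where the median was −0.06 and camera's direction down but the mean 0.13. Of 20 FGF-ERK genes 9 rose and 8 fell (17 adjusted over the list alone; median 0.06, mean −0.05, camera's direction down, adjusted p 0.943), and of 14 neuroectoderm genes 6 rose and 4 fell (10 adjusted over the list alone; median 0.54, adjusted p 0.59).

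The remaining lists passed in no comparison with wild type and held large changes of single members in both directions. Among formative and primed epiblast genes Lef1 and Sox4 (3.19, 3.47, 0.49 and 2.58) rose and Nodal fell (−2.44, −2.42, −1.93 and −0.94). Of 19 such genes 10, 11, 10 and 10 rose and 7, 6, 7 and 7 fell (17 in each adjusted over the list alone; adjusted p 0.423, 0.217, 0.407 and 0.28). Among germline genes silenced by DNA methylation, Sohlh2, a germ cell transcription factor, fell (−3.12, −3.25, −0.16 and −3.46), and the RNA-binding protein gene Dazl fell in Mettl3 (−1.16), Mettl14 (−1.77) and Zc3h13 (−1.79) knockouts and rose in Wtap knockout (1.54). Of 24 members 9, 7, 14 and 10 rose and 11, 10, 7 and 11 fell (20, 17, 21 and 22 adjusted over the list alone; adjusted p 0.526, 0.59, 0.151 and 0.469), and in Mettl14 knockout the median was 0.02 while the mean (−0.47) and camera pointed down. Plagl1, an imprinted zinc-finger gene, fell from 102 ± 3.5 CPM to 2.31 and 2.72 CPM in Mettl3 and Zc3h13 knockouts and was 96.1 ± 6.2 CPM in Wtap knockout (adjusted p = 0.337), and the noncoding RNA Rian fell (−1.96, −2.45, −0.83 and −3.25). Of 40 imprinted genes 20, 18, 17 and 16 rose and 17, 17, 15 and 22 fell (37, 35, 33 and 38 adjusted over the list alone; adjusted p 0.993, 0.993, 0.876 and 0.243).

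Hnf4a, a regulator of liver and visceral endoderm, fell from 13.4 ± 0.56 CPM (−5.15, −5.88, −1.62 and −4.18). Of 20 primitive endoderm genes 9, 11, 4 and 10 rose and 6, 6, 9 and 5 fell (15, 17, 13 and 15 adjusted over the list alone; adjusted p 0.606, 0.446, 0.423 and 0.457). The trophoblast factors Tead4 on chromosome 6 (−2.99, −3.04, −1.39 and −1.73) and Eomes (−2.59, −2.87, −0.82 and −0.52) fell, and Fgfr2 rose (4.65, 5.28, 2.36 and 3.70). Of 16 trophoblast genes 5 rose in each knockout and 8, 8, 6 and 9 fell (13, 13, 11 and 14 adjusted over the list alone; adjusted p 0.469, 0.511, 0.993 and 0.362). Their medians were −0.22, −0.19, 0.11 and −0.33, their means 0.27, 0.14, 0.10 and 0.13, and camera's direction was down in each. In the mesoderm and primitive streak list, Kdr, a receptor of VEGF, rose (2.65, 2.94, 0.55 and 4.22), and T, the brachyury gene, fell in Mettl14 (−2.63) and Zc3h13 (−3.11) knockouts and rose in Wtap knockout (0.47). Of 14 members 5, 6, 6 and 8 rose and 5, 6, 3 and 6 fell (10, 12, 9 and 14 adjusted over the list alone; adjusted p 0.893, 0.993, 0.59 and 0.511). Their medians were −0.21, 0.16, 0.36 and 0.66, with a mean of 0.12 in Mettl3 knockout and 0.04 in Mettl14 knockout, where camera's direction was down in both. Among markers of fibroblasts, the usual feeder cells of stem cell cultures, Dcn had 0 reads in wild type and Wtap knockout and was at least 42.0-, 45.7- and 54.4-fold higher than in wild type in Mettl3, Mettl14 and Zc3h13 knockouts, at 0.73, 0.80 and 0.96 CPM. Col1a1 fell in all 4, from 1.75 CPM (−2.43, −2.14, −2.85 and −1.68). Of 13 fibroblast and feeder genes 6, 6, 2 and 5 rose and 4, 3, 4 and 4 fell (10, 9, 6 and 9 adjusted over the list alone; adjusted p 0.736, 0.395, 0.646 and 0.715).

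Among interferon-stimulated genes Bst2 on chromosome 8 fell from 82.2 CPM (−2.6, −2.37, −2.18 and −1.81), Stat2 fell (−1.28, −1.54, −1.08 and −1.20), and Oas1a rose (1.18, 1.03, 1.22 and 1.43). Of 27 such genes 14, 15, 8 and 15 rose and 9, 9, 8 and 7 fell (25, 25, 16 and 24 adjusted over the list alone; adjusted p 0.487, 0.496, 0.949 and 0.166), and in Wtap knockout the median (0.03) and mean (0.20) were positive while camera's direction was down. Among cytoplasmic ribosomal proteins Rpl39l, a paralogue of the testis, rose in all 4 (1.74, 1.66, 3.18 and 1.99) and Rpl32 on chromosome 6 fell (−0.84, −0.96, −0.89 and −0.94). Of 90 ribosomal protein genes 30, 15, 20 and 17 rose and 17, 40, 9 and 32 fell (44, 54, 21 and 48 adjusted over the list alone), with medians of 0.07, −0.09, 0.03 and −0.06 (adjusted p 0.373, 0.243, 0.487 and 0.258). For the readers and erasers in Zc3h13 knockout the median was −0.04 and the mean 0.29, with camera's direction up.

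Comparisons between knockouts, whose contrasts leave out the wild-type group, asked where the losses of single subunits differ. The wild-type libraries still entered the filter and the estimate of spread. Each knockout had 2 libraries, which may come from the same cells. A difference between cell lines therefore cannot be told apart from an effect of the subunit. Of 144 tests of lists, 45 passed, and 0 with an estimated correlation. The two-cell-like list differed in all 6 pairs. It was lower in Mettl3 than in Mettl14 knockout (median −1.49, 0 higher and 14 lower, adjusted p = 3.32e-06), higher in Mettl3 than in Wtap (2.8, 17 and 0, 5.34e-06) and Zc3h13 knockouts (0.75, 12 and 0, 0.00731), higher in Mettl14 than in Wtap (3.91, 19 and 0, 2.55e-07) and Zc3h13 knockouts (2.22, 18 and 0, 7.52e-07), and lower in Wtap than in Zc3h13 knockout (−1.75, 0 and 13, 0.000648). In the same order, adjusted p = 0.344, 0.344, 0.422, 0.344, 0.344 and 0.416 with an estimated correlation. The neuroectoderm list was higher in Mettl14 than in Wtap (median 1.93, adjusted p = 0.00411, and adjusted p = 0.416 with an estimated correlation) and Zc3h13 knockouts (1.40, adjusted p = 0.000352, and adjusted p = 0.372 with an estimated correlation). In Mettl3 knockout it was lower than in Mettl14 (−0.50, adjusted p = 0.045, and adjusted p = 0.492 with an estimated correlation) and higher than in Wtap (1.26, adjusted p = 0.0167, and adjusted p = 0.422 with an estimated correlation) and Zc3h13 knockouts (0.55, adjusted p = 0.0201, and adjusted p = 0.422 with an estimated correlation). Ribosomal protein genes were higher in Mettl3 than in Mettl14 (0.15, adjusted p = 3.25e-05, and adjusted p = 0.659 with an estimated correlation) and Zc3h13 knockouts (0.14, adjusted p = 0.000125, and adjusted p = 0.705 with an estimated correlation). Glycolysis genes were lower in Mettl3 than in Wtap knockout (−0.37, adjusted p = 0.00411, and adjusted p = 0.589 with an estimated correlation). The writer complex list was higher in Mettl14 than in Zc3h13 knockout (0.34, adjusted p = 0.00214, and adjusted p = 0.344 with an estimated correlation). That list includes Zc3h13 and Mettl14 themselves, and Zc3h13 was reduced in its own knockout, so part of the difference was fixed by the design. The germline list was higher in Wtap than in Zc3h13 knockout (0.69, adjusted p = 0.000557, and adjusted p = 0.344 with an estimated correlation). WNT targets were higher (0.63, adjusted p = 6.57e-05, and adjusted p = 0.344 with an estimated correlation) and FGF-ERK genes lower (−0.69, adjusted p = 6.05e-05, and adjusted p = 0.409 with an estimated correlation) in Mettl3 than in Zc3h13 knockout.

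Mettl3 and Mettl14, which form the catalytic pair, had the fewest genes apart: 7879 genes, 4199 higher and 3680 lower in Mettl3 knockout, of which 1258 differed at least 2-fold, and 5199 genes (2198 lower) without Mettl3 knockout replicate 1. Zdbf2, an imprinted gene, was lower in Mettl3 (11.8 ± 0.27 CPM) than in Mettl14 knockout (83.5 ± 22 CPM; −2.83, SE 0.15), and Rhox2b, of a multi-copy family, was higher (3.17). Mettl3 and Wtap knockouts differed in 11027 genes (5610 higher, 5417 lower; 3229 at least 2-fold), among them the neural genes Insm1, with 1.53 ± 0.28 against 0.030 CPM, and Zfhx4, with 9.71 ± 0.21 against 0.31 CPM, and Xlr5a, with 0.11 against 18.4 ± 0.48 CPM. Mettl3 and Zc3h13 knockouts differed in 8724 genes (4527 higher, but 2984 without Zc3h13 knockout replicate 2, and 4197 lower; 1793 at least 2-fold), with Ptn at 21.1 against 1.29 ± 0.32 CPM and Gpnmb, a transmembrane glycoprotein gene on chromosome 6, at 1.00 against 12.3 ± 0.19 CPM. Mettl14 and Wtap knockouts differed in 12344 genes (5962 higher, 6382 lower; 4233 at least 2-fold), with Insm1 (7.0, SE 0.32) and the axon guidance gene Sema5a at 6.87 ± 0.47 against 0.13 CPM. Mettl14 and Zc3h13 knockouts differed in 10114 genes (4938 higher, 5176 lower; 2577 at least 2-fold), with Evc2, a gene of the cilium, at 3.68 against 0.11 CPM and Cited4 at 0.73 ± 0.33 against 11.6 ± 0.66 CPM. Wtap and Zc3h13 knockouts differed in 11661 genes (5790 higher, 5871 lower; 3313 at least 2-fold), with Xlr5b (8.81) higher and Sema6d (−5.32, SE 0.28) lower in Wtap knockout. Which direction held more genes depended on the scaling and on single libraries. Relative log expression scaling gave 3803 higher and 4131 lower between Mettl3 and Mettl14 knockouts, and leaving out Mettl14 knockout replicate 2 gave 3285 and 4226 and Wtap knockout replicate 1 3875 and 4063. Between Mettl14 and Zc3h13 knockouts this scaling gave 5619 higher and 4749 lower, and the larger direction turned without Mettl3 knockout replicate 2 (5207 and 4571), Mettl14 knockout replicate 1 (5016 and 4796) or replicate 2 (5704 and 4224) or Wtap knockout replicate 1 (5575 and 4822). Families that differed numbered 261, 278, 191, 442, 447 and 292 in the same order of pairs. In the knockout named first, 248, 72, 45, 53, 35 and 151 were higher and 13, 206, 146, 389, 412 and 141 lower. Most were thus lower in Mettl14 knockout in each of its pairs.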

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

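The tests on chromosomes 6 and 8 and on IAPEz-int were chosen after the results had been seen. The two-cell-like list moved in opposite directions in different knockouts. Its median log2 fold change against wild type was 1.61 in Mettl3 and −0.88 in Wtap knockout, and the list differed between them by a median of 2.8 (camera adjusted p = 5.34e-06, and adjusted p = 0.344 with an estimated correlation). Between Mettl14 knockout (2.94) and Wtap knockout the median difference was 3.91 (adjusted p = 2.55e-07, and adjusted p = 0.344 with an estimated correlation). The comparison with wild type did not pass under the filter of at least 1 CPM in 2 libraries in Mettl3 (0.0513) and Wtap (0.0912) knockouts, nor in Wtap knockout with voom weights (0.165) or without its replicate 2 (0.0515), and MERVL-int, a marker of the same state, fell in Mettl3 (−0.77) and Mettl14 (−0.55) knockouts. Part of the fall of MERVL-int in Mettl14 knockout was common to repeats, as all 990 families had a median of −0.22 there. The X-linked Xlr5a rose in Wtap knockout (1.05) and fell in Zc3h13 knockout (−7.21), a difference of 8.27 between them (edgeR adjusted p = 3.94e-13). Xlr5c likewise rose in Wtap knockout (1.34) and fell in Zc3h13 knockout (−6.71), a difference of 8.05 (adjusted p = 3.3e-11). Both belong to a multi-copy family, in which the assignment of reads is uncertain.

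Genes of chromosomes 6 and 8 were for the most part lower in all 4 knockouts than in wild type. Independent regulation of single genes was argued against by random lists matched on expression, of which 0 in 10000 had a median as low as that of either chromosome in any comparison. The fall ran along chromosome 6, where the highest median of a 20 Mb window against wild type was −0.22, and along chromosome 8, where it was −0.10, and the comparisons among knockouts had chromosome 6 medians within 0.04 of 0. This is consistent with a different number of copies of both chromosomes in the wild-type cells, a candidate explanation that needs a karyotype or DNA reads. No biological explanation was tested.

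IAPEz-int was higher in all 4 knockouts than in wild type. More reads from repeats of every kind were argued against as the source of the rise. The median of SINE families was at most 0.058 of the log2 fold change of IAPEz-int, though SINE reads may come from copies inside genes. All 990 families had medians of −0.01, −0.22, 0.05 and 0.10 in Mettl3, Mettl14, Wtap and Zc3h13 knockouts. The loss of m6A from IAP transcripts may raise their level, and a difference between the parental cells of the knockouts and the wild-type cells may do so too. The rises were unequal among the knockouts, by up to 0.60 for IAPEz-int, but a part common to all 4 cannot be told apart from a difference of the single wild-type line. The 0.60 lies between Mettl14 and Zc3h13 knockouts. There all families had a median of −0.32 and SINE families −0.24, so that not all of it was particular to IAPEz-int.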

How the results depend on the processing

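The setting without genes of chromosomes 6 and 8 was chosen after the data had been seen. Named genes were tested again with relative log expression scaling, DESeq2, limma-voom, the filter of at least 1 CPM in 2 libraries, the replicate block and each library left out. Most were picked for large changes or a small adjusted p in the same libraries, so that kept calls were likely from the start. They say little about the other genes. Named genes that passed in the main setting or the other one kept their direction. Direction was not compared where neither passed. Of the tests of named genes, 7871 kept the call while 8 did not. These were Usp17lb in Wtap knockout (adjusted p 0.0616 with DESeq2, and 0.0897, 0.052 and 0.109 without wild-type replicate 1, wild-type replicate 2 and Wtap knockout replicate 2), Mettl3 in Wtap knockout without wild-type replicate 1 (0.0563), Mettl14 in Mettl3 knockout without wild-type replicate 2 (0.124) and without Mettl3 knockout replicate 1 (0.16), and Zc3h13 in Mettl3 knockout without Mettl3 knockout replicate 2 (0.0748). Named families kept their call in 4801 tests, lost it in 98 and gained it in 93. List directions kept their call in 1674 tests, lost it in 39, gained it in 14 and reversed in 1, the histone list in Mettl3 knockout, with a median of 0.38 over 7 members under the filter of at least 1 CPM in 2 libraries, where fewer genes were tested. Under that filter the two-cell-like list in Mettl3 (0.0513) and Wtap (0.0912) knockouts, the writer list (0.0912) and the neuroectoderm list (0.177) in Mettl14 knockout, the histone list in Wtap knockout (0.0686) and in Zc3h13 knockout, where its median was −0.29, and the mitochondrial mRNAs in Zc3h13 knockout (0.0686) did not pass either. The writer list in Mettl14 knockout did not pass with upper-quartile scaling (0.0548), nor the two-cell-like list in Wtap knockout with voom weights (0.165). Without a filter FGF-ERK genes in Mettl3 knockout, WNT targets and histones in Mettl14 knockout, germline genes and p53 targets in Wtap knockout and interferon-stimulated genes in Zc3h13 knockout passed too. The estimated correlation was used only with the main settings and without genes of chromosomes 6 and 8. The cause was not tested. The median fold change of all genes lay between −0.032 and 0.059 under every scaling. The split of calls into higher and lower depended on the scaling, and the larger direction of several comparisons turned with it, as in Mettl14 knockout against wild type, with 7325 higher and 7157 lower under relative log expression scaling and 7611 and 6906 under upper-quartile scaling. Depth limits the genes with few reads in wild type, whose fold changes are bounds or count ratios.

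Requiring an absolute log2 fold change of at least 1 left 6072, 6576, 3966 and 6034 genes in Mettl3, Mettl14, Wtap and Zc3h13 knockouts, 5505 for their mean, 2383 alike in all 4, and 1258, 3229, 1793, 4233, 2577 and 3313 between pairs of knockouts, in the order of the report, since fewer genes can meet it. With an estimated correlation 0 lists passed in each comparison with wild type, against 6 with the preset one. Correlations of fold changes were 0.946, 0.811, 0.916, 0.734, 0.891 and 0.785 under the filter of at least 1 CPM in 2 libraries, which leaves out weakly expressed genes. Leaving out each library in turn gave ranges of 0.888 to 0.929, 0.688 to 0.800, 0.872 to 0.905, 0.604 to 0.721, 0.834 to 0.874 and 0.667 to 0.783 for these correlations. In such fits a lone library is assumed to vary like the other groups. They gave 12581 to 14747, 13388 to 14805, 10711 to 12888 and 12978 to 14894 genes in the 4 knockouts, 6942 to 8183 alike in all 4, and 5199 to 7957 genes between Mettl3 and Mettl14 knockouts, the lowest without Mettl3 knockout replicate 1, and 314 to 434, 416 to 529, 260 to 336 and 333 to 452 repeat families in the 4 knockouts. With the replicate number as a block 13890, 14364, 12036 and 14119 genes changed, but deviations of replicates from their group means correlated at only −0.11 to 0.04 between groups, so that the numbers do not pair the libraries. Taking genes of chromosomes 6 and 8 out of the main calls left 12786, 13193, 10987 and 12998 changed genes, 7037 alike in all 4. Scaling, spread and adjustment were not redone, so these counts follow by subtraction and do not test the other calls. The camera tests were repeated on the remaining genes with the same scaling. In them 6, 8, 6 and 6 lists passed, but 0 with an estimated correlation (lowest adjusted p = 0.473).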

Other observations

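The test of junction density was written down before its result was seen. Oasl2, an interferon-stimulated gene, rose from 0.034 ± 0.030 CPM to 2.24 ± 0.29, 0.36 ± 0.11, 0.98 ± 0.0070 and 3.35 ± 0.17 CPM in Mettl3, Mettl14, Wtap and Zc3h13 knockouts (SD, n = 2). The imprinted noncoding RNA H19 rose in Wtap knockout from 0.14 to 3.08 CPM (4.44). The long terminal repeat RLTR13B2 fell from 88.8 ± 1.9 CPM to 3.91, 4.01, 8.41 and 7.67 CPM.

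Transcripts with few exon junctions per kb of coding sequence were higher in the knockouts, and loss of m6A from long-exon transcripts could raise them, since m6A lies mostly in long exons and shortens the life of mRNA. Among 10152 genes outside chromosomes 6 and 8, which were 82.7% of those eligible, Spearman's rho between fold change and junction density was −0.26, −0.25, −0.18 and −0.26 in Mettl3, Mettl14, Wtap and Zc3h13 knockouts, and the value nearest to 0 was −0.181. Given transcript length, GC content and expression level, the partial rho was −0.27, −0.26, −0.21 and −0.25, so that these do not account for the relation, the weakest value being −0.2123. In the 2538 genes with the lowest density the median fold change was 0.39, 0.43, 0.22 and 0.42, and in as many with the highest −0.10, −0.11, −0.02 and −0.13. Genes are not independent replicates, and a difference between the parental cells stays open for this relation too. Between knockouts, rho was 0.21 for Wtap against Zc3h13 knockout, and −0.21 and −0.19 for Mettl3 and Mettl14 against Wtap knockout. In the pairs without Wtap knockout it was 0.05, 0.02 and −0.02. Differences between cell lines and effects of the subunit cannot be told apart in these pairs either.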
